A study of Arabidopsis thaliana with 10 samples.

How the data were processed

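RNA was measured in 10 libraries of whole Arabidopsis thaliana seedlings, 2 biological replicates of each of 5 genotypes, all grown for 4 days in continuous blue light of 1 µmol m-2 s-1. Per the labels' protocols, poly(A) RNA was made into libraries with a directional kit, and whether the strand was used in counting is not given in the sources used here. Per the submitters' processing notes, STAR (version not given) and Cufflinks 2.1.1 were used with the TAIR10 genome. Each library has a table of deposited FPKM values (fragments scaled to transcript length and to the mapped fragments of the library), estimated by the authors for 33557 genes, per the file headers. Coordinates are those of the files, on TAIR10, written from 1. Of the genes, 32810 matched a locus tag in the reference annotation used for names, and 10573 had the same start and end there, so coordinates come from the files alone.

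The files mark an estimate as failed or skipped in 15 entries at 10 loci and list it at 0. These entries were treated as missing, and UBP12 in ubp12ubp13 replicate 2 is among them. The confidence bounds in the files were not used, because FPKM lay above its own upper bound for 3751 to 5823 genes per library. FPKM are not counts, so no count test was run, and the planned count-based alternatives were left out. Depth was estimated from 4626 genes without introns of 800 to 4000 bp. Values of up to 6 fragments were used, and 97.9% to 99.7% of the 299 to 385 values per library came out whole within 0.1 fragment with a length offset of 210 bp. It ranged from 15.9 to 31.2 M fragments, and the floor of 3 fragments covers counting error only. Deeper libraries give smaller errors for low genes, and short loci have unstable FPKM at any of these depths. Genes that overlap another locus, such as CHS, F3H, ESB1, CASP1, LHCB3, ATMRD1 and AT1G52690, may hold fragments of that locus, and near-identical family members such as the RBCS, LHCB1 and SAUR genes may share theirs, so both are uncertain.

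Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. Values were tested as log2(FPKM + 1), so fold changes understate the change of low genes. Genes with 1 FPKM or more in at least 2 libraries were kept (19957). All 10 libraries entered a single limma-trend fit with a mean per genotype (5 residual and 3.15 prior degrees of freedom). Tests were two-sided, with Benjamini-Hochberg adjustment within each of 8 comparisons and calls at an adjusted p of 0.05. Rescaling by the median of ratios, with factors from 0.933 in WT replicate 1 to 1.06 in UBP13oe replicate 2, was run as an alternative. Its counts (rescaled) are given because it moved the split of higher and lower calls. In simulations of 19947 genes, 67, 67 and 66 were given changes of 0.5, 1 and 2 on the log2 scale. In the 4 comparisons against WT the fit recovered 46.3% to 58.2%, 82.1% to 94.0% and 92.4% to 97.0% of these, and 3.80% to 5.85% of calls were false. The data had far more calls, so these shares may not carry over.

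Gene lists were fixed before the data were examined. There were 17, covering light signalling, phytochrome-interacting factor and shade genes, auxin response, cell wall expansion, brassinosteroid and gibberellin, flavonoid, nuclear photosynthesis, tetrapyrrole, clock, flowering, jasmonate, salicylate defence, abscisic acid and cold, heat shock and cell cycle genes, with root markers and seed markers for other organs or ungerminated seed. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 102 tests in 6 comparisons, and again with an estimated correlation. Camera compares a list with all other genes, so a list can be called down while its median is above 0. Genes were named by a rule fixed at the same time. It took CRY2, CRY1, UBP12 and UBP13, then in each comparison against WT the 8 largest called rises and falls at 5 FPKM or more in the higher genotype, with both libraries beyond both WT libraries. It also took up to 4 called members per list with the smallest adjusted p, the 5 genes with the largest shared and opposite changes in the comparisons without WT, and 5 gene models on each side of CRY2, UBP12 and UBP13. The report gives examples from the lists, and 1 named gene is not reported here. Named loci under 300 bp were left out after their values were seen. Counts of a list without 1 library are given where the larger of rose and fell moved by more than 1.5 times, or the smaller did by at least 2 genes.

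Alternatives were a pseudocount of 0.1, no filter, a stricter filter on a mean of 5 FPKM, the median-of-ratios rescaling, a replicate block, a fit of only the libraries compared, a variance without trend and leaving out each library in turn. Leaving out a library leaves a genotype with 1 library, which is then assumed to vary like the other genotypes. Taking failed estimates as 0 and using nuclear genes alone were added after seeing the data. Covariances of fold changes that share WT were set beside those of 50 simulations of unchanged groups.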

Results

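Messenger RNA was measured by sequencing in whole Arabidopsis thaliana seedlings grown for 4 days under continuous blue light of 1 µmol m-2 s-1. The 10 libraries came from 5 genotypes with 2 biological replicates each. These were the Columbia wild type (WT), cry2-1, which lacks the blue-light receptor CRY2, a CRY2 overexpressor (CRY2oe), a UBP13 overexpressor (UBP13oe) and the line labelled ubp12ubp13, a double mutant of the deubiquitinase genes UBP12 and UBP13. The series asks, by its title, how these deubiquitinases act on CRY2 and on growth. Gene levels were the deposited FPKM values, given as mean ± SD of the 2 libraries of a genotype unless stated otherwise. Depth, estimated from the smallest steps between low FPKM values, ranged from 15.9 M fragments in ubp12ubp13 replicate 2 to 31.2 M in UBP13oe replicate 1. At that depth, 3 fragments on 1 kb of transcript corresponded to between 0.0962 and 0.189 FPKM, by counting error alone. Each library had between 18557 and 19206 genes at 1 FPKM or more. Log2(FPKM + 1) values of replicates correlated across genes at 0.983 to 0.989, and those of different genotypes at 0.929 to 0.975. Plastid-encoded genes held 8.57% and 11.2% of all FPKM in the WT libraries, 16.9% and 17.59% in cry2-1, 18.0% and 17.9% in CRY2oe, 9.06% and 9.58% in UBP13oe, and 16.2% and 15.5% in the libraries labelled ubp12ubp13.

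CRY2 (AT1G04400, TAIR10 chromosome 1, 1185550 to 1188517) was listed at 0 and at 0.0187 FPKM in the cry2-1 libraries and stood at 3865 ± 81.2 against 115 ± 7.19 FPKM in CRY2oe and WT (n = 2 each). In UBP13oe CRY2 was at 96.3 ± 0.197 against 115 ± 7.19 FPKM in WT (log2 fold change -0.25 ± 0.05 (SE), limma adjusted p = 0.00485), and in the libraries labelled ubp12ubp13 at 85.9 ± 2.62 FPKM (log2 fold change -0.41 ± 0.05 (SE), limma adjusted p = 0.000194). UBP13 (AT3G11910, TAIR10 chromosome 3, 3761388 to 3770563) was at 67.6 ± 2.06 against 27.7 ± 0.833 FPKM in UBP13oe and WT (log2 fold change 1.26 ± 0.05 (SE), limma adjusted p = 1.46e-05). The libraries labelled ubp12ubp13 still held UBP13 at 23.9 ± 0.416 against 27.7 ± 0.833 FPKM in WT (log2 fold change -0.20 ± 0.05 (SE), limma adjusted p = 0.00664). UBP12 (AT5G06600, TAIR10 chromosome 5, 2019107 to 2027945) was at 34.9 ± 0.181 FPKM in WT, at 397 FPKM in ubp12ubp13 replicate 1, and had a failed estimate in replicate 2. These transcript levels do not by themselves show loss of either gene, and they do not test the genotype of the line. Taking the failed estimate as 0 turned the UBP12 change from 3.47 to -0.85 on the log2 scale. The first rests on 1 library, with the spread of the other genotypes (limma adjusted p = 2.08e-07), and the second did not pass the test. The files give 1 value per gene and do not show which part of either gene the fragments came from, so these libraries are called the libraries labelled ubp12ubp13. CRY1 (AT4G08920, TAIR10 chromosome 4, 5724103 to 5727253), the related blue-light receptor, was lower than in WT (95.3 ± 5.66 FPKM) in each of the other genotypes, between 75.9 FPKM in CRY2oe and 83.9 FPKM in UBP13oe. Its call was lost without WT replicate 2 in UBP13oe and in ubp12ubp13, and without UBP13oe replicate 2, with a limma adjusted p of up to 0.101.

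**Figure D1:**
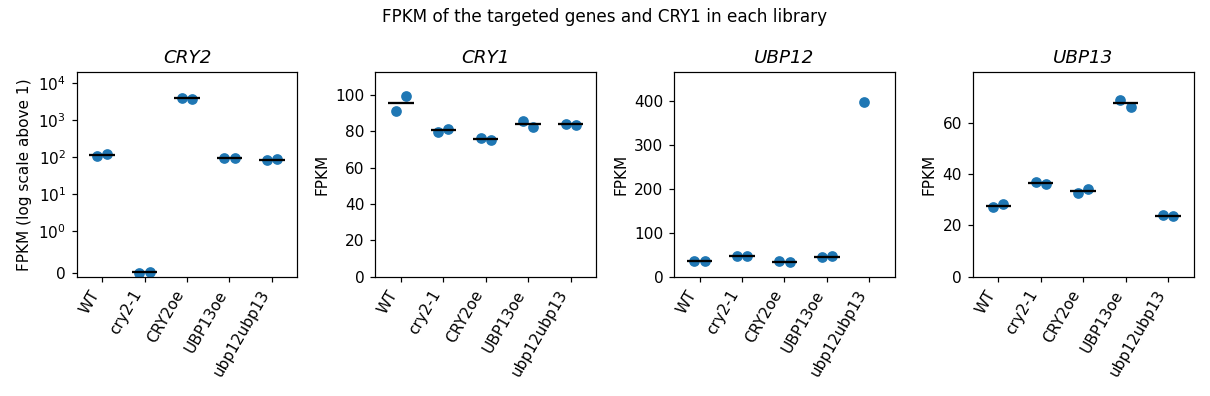
FPKM of CRY2, CRY1, UBP12 and UBP13 (vertical axes, on a log scale above 1 FPKM for CRY2) in the 2 libraries of each of the 5 genotypes (points), with the mean as a bar. UBP12 has a single point for ubp12ubp13, at 397 FPKM, because its other estimate failed.

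Of the 10 measured gene models beside CRY2, 3 rose and 3 fell in cry2-1, and 4 rose and 2 fell in CRY2oe (2 and 3 rescaled). The 2 gene models after CRY2 were near 0 in both genotypes. AT1G04410, a cytosolic malate dehydrogenase gene at 1189078 to 1191412 on chromosome 1, was listed at 0 in both cry2-1 libraries and stood at 0.0853 ± 0.0409 FPKM in CRY2oe, against 439 ± 6.13 FPKM in WT. AT1G04420, at 1191608 to 1193884, was listed at 0 in all 4 libraries against 31.1 ± 1.18 FPKM in WT. AT1G04425, a non-coding RNA gene, rose to 8.14 ± 0.215 FPKM in cry2-1 and 54.6 ± 4.5 FPKM in CRY2oe from 2.46 ± 0.0710 FPKM in WT. In cry2-1 AT1G04430 and CKL13 also rose and AT1G04350 fell. In CRY2oe AT1G04360, AT1G04430 and CKL13 rose, and each of these calls was lost without either WT library or without CRY2oe replicate 1 (AT1G04360 and CKL13 also without CRY2oe replicate 2). Beside UBP12, 3 of 10 gene models rose and 3 fell (2 and 3 rescaled) in the libraries labelled ubp12ubp13, where AT5G06560, AT5G06570 and AT5G06580 were the ones that fell. The call was lost for AT5G06630 without ubp12ubp13 replicate 2 (limma adjusted p = 0.0691) and for AT5G06640 without WT replicate 2 or any cry2-1, UBP13oe or ubp12ubp13 library (up to 0.102). Beside UBP13, 4 rose and 1 fell in those libraries (2 and 3 rescaled). ATHST (42.3 ± 0.771 against 21.2 ± 0.986 FPKM) and ANT1 rose, and AT3G11930 fell (139 ± 3.29 against 237 ± 0.654 FPKM). Calls beside UBP13 were lost for PUB24 without any WT, cry2-1 or UBP13oe library or ubp12ubp13 replicate 2 and for AT3G11950 without WT or ubp12ubp13 replicate 2. In UBP13oe 4 rose and 1 fell there too (0 and 2 rescaled), with rises lost without any WT, UBP13oe or ubp12ubp13 library (limma adjusted p up to 0.211). Beside CRY2, 5 rose and 2 fell in the libraries labelled ubp12ubp13 (3 and 2 rescaled), with calls lost without WT replicate 1 or either ubp12ubp13 library.

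Loss of CRY2 was examined by comparing cry2-1 with WT. PORA and PORB, which encode light-dependent protochlorophyllide oxidoreductases of chlorophyll synthesis, were higher in cry2-1, at 154 ± 0.642 against 2.94 ± 1.93 FPKM in WT and 515 ± 32.1 against 105 ± 13 FPKM. XTH17, a xyloglucan-modifying cell wall enzyme, was at 252 ± 13.4 against 52.4 ± 7.01 FPKM. The cold-response gene COR15B was at 0.381 ± 0.0697 against 47 ± 15.3 FPKM, and AT4G26530, a fructose-bisphosphate aldolase gene, at 10.2 ± 1.61 against 382 ± 16.8 FPKM. limma called 8694 of 19956 genes, 6331 higher and 2363 lower in cry2-1. The median log2 change of all genes was 0.12 (-0.01 rescaled). Rescaled, 3299 were called higher and 4069 lower, 5662 with the same sign in both.

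The chlorophyll and heme (tetrapyrrole) list was higher in cry2-1. In it 20 of 23 rose and 1 fell (20 and 1 adjusted over the list alone, 17 and 1 rescaled), with a median 0.41 above that of all genes on the log2 scale. Camera put tetrapyrrole genes above others (adjusted p = 5.71e-07, or adjusted p = 0.296 with estimated correlation). Besides PORB these included the chlorophyllide oxygenase gene CAO at 86 ± 0.292 against 56 ± 1.00 FPKM and the magnesium chelatase gene CHLI1 at 129.7 ± 3.39 against 88.9 ± 2.33 FPKM. Of 20 cell cycle genes, 19 rose and 0 fell (19 and 0 adjusted over the list alone, 17 and 0 rescaled), among them the cytokinesis syntaxin KNOLLE at 47.3 ± 1.8 against 26.5 ± 0.521 FPKM. Camera put cell cycle genes above others (adjusted p = 2.61e-05, or adjusted p = 0.392 with estimated correlation). In the cell wall expansion list, 16 of 25 rose and 2 fell (17 and 3 adjusted over the list alone, 14 and 5 rescaled). XTH30 stood at 256 ± 7.55 against 160.1 ± 7.32 FPKM. Camera put cell wall expansion genes above others (adjusted p = 0.0178, or adjusted p = 0.307 with estimated correlation). Of the phytochrome-interacting factor and shade genes, 15 of 29 rose and 2 fell (16 and 2 adjusted over the list alone, 11 and 2 rescaled). PIF3 stood at 24 ± 0.487 against 10.9 ± 0.293 FPKM and IAA19 at 96.2 ± 4.57 against 43.4 ± 3.74 FPKM. That list missed the threshold (camera adjusted p = 0.0604). Of the auxin response genes, 16 of 36 rose and 4 fell (17 and 5 adjusted over the list alone, 7 and 7 rescaled). For this list the camera adjusted p was 0.175. IAA20 stood at 33.2 ± 1.94 against 5.15 ± 0.0216 FPKM. The shade list passed with no filter (camera adjusted p = 0.0494), with the stricter filter (0.0417), after rescaling (0.0286), with only the libraries compared (0.0284), without cry2-1 replicate 1 (0.0403), CRY2oe replicate 1 (0.0466) or 2 (0.0458) or ubp12ubp13 replicate 1 (0.0451) or 2 (0.0494). The auxin response list passed with only the libraries compared (camera adjusted p = 0.0332).

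Of 28 clock genes, 2 rose and 15 fell in cry2-1 (3 and 15 adjusted over the list alone, 2 and 19 rescaled). Camera put clock genes below others (adjusted p = 5.71e-07, or adjusted p = 0.296 with estimated correlation). The evening gene ELF4 was at 42 ± 0.784 against 106 ± 1.87 FPKM, TOC1 at 52.1 ± 0.647 against 102 ± 5.19 FPKM and the blue-light F-box gene FKF1 at 5.45 ± 0.501 against 17.2 ± 0.337 FPKM. Of 21 abscisic acid (ABA) and cold genes, 1 rose and 10 fell (1 and 11 adjusted over the list alone, 1 and 14 rescaled), led by COR15B and COR413IM1 (116 ± 7.25 against 293 ± 22.4 FPKM). Camera put ABA and cold genes below others (adjusted p = 6.94e-07, or adjusted p = 0.296 with estimated correlation). Of 47 nuclear photosynthesis genes, 8 rose and 21 fell (9 and 22 adjusted over the list alone, 4 and 24 rescaled), while the plastid-encoded share of FPKM was higher than in WT. Camera put photosynthesis genes below others (adjusted p = 7.29e-06, or adjusted p = 0.514 with estimated correlation). PSBO2 of photosystem II was at 284 ± 2.45 against 536 ± 8.44 FPKM and LHCB7 at 9.92 ± 0.635 against 24.9 ± 0.935 FPKM. In the flavonoid list, 3 of 15 rose and 8 fell (3 and 8 adjusted over the list alone, 2 and 8 rescaled), chalcone synthase (CHS) being at 1.34 ± 0.0556 against 7.57 ± 2.02 FPKM. Camera put flavonoid genes below others (adjusted p = 0.00224, or adjusted p = 0.346 with estimated correlation). The light signalling list held HY5, a transcription factor that promotes photomorphogenesis, at 20.6 ± 0.384 against 41.5 ± 1.83 FPKM and the cryptochrome inhibitor gene BIC1 at 2.35 ± 0.355 against 9.52 ± 1.09 FPKM. In it, 8 of 28 rose and 10 fell (8 and 11 adjusted over the list alone, 7 and 13 rescaled). Camera put light signalling genes below others (adjusted p = 0.0147, or adjusted p = 0.346 with estimated correlation). Of 10 flowering genes, 1 rose and 5 fell (1 and 5 adjusted over the list alone, 0 and 5 rescaled), the floral repressor FLC being at 24.5 ± 0.637 against 59.8 ± 2.18 FPKM. Camera put flowering genes below others (adjusted p = 0.00169, or adjusted p = 0.295 with estimated correlation). In the photosynthesis list 5 rose and 20 fell without cry2-1 replicate 2.

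Among root markers, 7 of 18 rose and 1 fell (7 and 1 adjusted over the list alone, 6 and 3 rescaled) in cry2-1 (camera adjusted p = 0.753), the risers including ESB1 and CASP5 of the endodermal Casparian strip (157 ± 2.77 against 73.3 ± 4.72 FPKM for CASP5). Of 9 seed markers, 1 rose and 2 fell (0 and 2 adjusted over the list alone, 0 and 2 rescaled). EM1 stood at 1.88 ± 0.0666 against 4.3 ± 0.568 FPKM. Camera put seed marker genes below others (adjusted p = 0.0351, or adjusted p = 0.503 with estimated correlation). Of 21 brassinosteroid (BR) and gibberellin (GA) genes, 7 rose and 4 fell (7 and 4 adjusted over the list alone, 3 and 6 rescaled). Of 18 jasmonate genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 2 and 2 rescaled). Of 12 salicylate defence genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone, 2 and 0 rescaled). Of 8 heat shock genes, 3 rose and 0 fell (4 and 0 adjusted over the list alone, 3 and 0 rescaled). The camera adjusted p of these 4 lists ranged from 0.257 to 0.97. For the BR and GA list the median and mean were above 0 and the test direction was down. Other large rises were ATMRD1 (30.8 ± 1.45 against 0.0593 ± 0.0839 FPKM) and the plastid RNA polymerase genes RPOC1 (58 ± 1.9 against 4.73 ± 1.68 FPKM) and RPOC2, and another large fall was AT3G11110 (1.05 ± 0.126 against 20.9 ± 0.785 FPKM). The seed marker call was lost with a pseudocount of 0.1 (camera adjusted p = 0.0575), with the stricter filter (0.859), after rescaling (0.254), without WT replicate 1 (0.282), cry2-1 replicate 2 (0.0547) or ubp12ubp13 replicate 1 (0.0614) or 2 (0.0686). In the root marker list 6 rose and 5 fell without WT replicate 2. In the seed marker list 5 fell without WT replicate 2, and 1 fell without either cry2-1 library. In the BR and GA list 4 rose without WT replicate 2 or cry2-1 replicate 1. In the jasmonate list 4 rose without either ubp12ubp13 library or cry2-1 replicate 1. In the heat shock list 5 rose without WT replicate 2.

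CRY2oe was compared with WT, with the same limit (AT1G04410 and AT1G04420 near 0). CHS, which encodes the first enzyme of flavonoid synthesis, was at 81.2 ± 7.15 against 7.57 ± 2.02 FPKM (log2 fold change 3.28 ± 0.19 (SE), limma adjusted p = 9.87e-05), and flavonol synthase (FLS1) was at 21.2 ± 0.35 against 3.27 ± 1.43 FPKM. The light-stress genes ELIP1 and ELIP2 were at 9.47 ± 1.28 against 2.21 ± 0.713 FPKM and 8.69 ± 0.978 against 2.01 ± 0.917 FPKM. The late embryogenesis gene LEA4-5 was at 5.15 ± 2.81 against 24.7 ± 3.44 FPKM and the oleosin family gene AT2G25890 at 3.54 ± 2.74 against 17.5 ± 3.57 FPKM. limma called 5224 of 19955 genes, 3302 higher and 1922 lower. Rescaled, 2165 were called higher and 3003 lower, 4087 with the same sign in both. The count fell to 2662 without CRY2oe replicate 1 and 2152 without CRY2oe replicate 2, and to 2194 when only the 4 libraries compared were fitted.

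Of 15 flavonoid genes, 10 rose and 0 fell in CRY2oe (12 and 0 adjusted over the list alone, 10 and 0 rescaled), with a median 0.88 above that of all genes on the log2 scale. Camera put flavonoid genes above others (adjusted p = 6.89e-07, or adjusted p = 0.295 with estimated correlation). Of 47 nuclear photosynthesis genes, 24 rose and 1 fell (30 and 1 adjusted over the list alone, 15 and 1 rescaled), including the light-harvesting genes LHCB5 at 2908 ± 15.1 against 1912 ± 56.4 FPKM and LHCB3 at 2666 ± 182 against 1578 ± 176 FPKM. Camera put photosynthesis genes above others (adjusted p = 6.99e-07, or adjusted p = 0.482 with estimated correlation). The plastid-encoded share of FPKM was also higher. For tetrapyrrole genes, 11 of 23 rose and 2 fell (12 and 2 adjusted over the list alone, 3 and 3 rescaled). Camera put tetrapyrrole genes above others (adjusted p = 0.0233, or adjusted p = 0.456 with estimated correlation). CHLH stood at 164 ± 2.22 against 128 ± 5.78 FPKM. Of 36 auxin response genes, 0 rose and 13 fell (0 and 14 adjusted over the list alone, 0 and 16 rescaled), among them IAA3 at 52.4 ± 2.64 against 82 ± 4.6 FPKM. Camera put auxin response genes below others (adjusted p = 2.53e-07, or adjusted p = 0.346 with estimated correlation). Of 20 BR and GA genes, 0 rose and 8 fell (1 and 9 adjusted over the list alone, 0 and 9 rescaled), the DELLA gene RGA being at 57.6 ± 2.34 against 75.8 ± 1.14 FPKM. Camera put BR and GA genes below others (adjusted p = 0.00318, or adjusted p = 0.296 with estimated correlation). In the cell wall expansion list, 2 of 25 rose and 8 fell (2 and 9 adjusted over the list alone, 2 and 11 rescaled). Camera put cell wall expansion genes below others (adjusted p = 0.0109, or adjusted p = 0.303 with estimated correlation). EXPA8 stood at 139.6 ± 10.1 against 224 ± 9.07 FPKM. Of 21 ABA and cold genes, 0 rose and 7 fell (1 and 8 adjusted over the list alone, 0 and 8 rescaled). Camera put ABA and cold genes below others (adjusted p = 0.00243, or adjusted p = 0.381 with estimated correlation). RD29B stood at 15.2 ± 3.1 against 47.4 ± 14.9 FPKM. The tetrapyrrole call was lost after rescaling (camera adjusted p = 0.0895) or without WT replicate 2 (0.132). In the photosynthesis list 13 rose without WT replicate 2, 9 rose without CRY2oe replicate 1, and 11 rose without CRY2oe replicate 2. In the tetrapyrrole list 7 rose and 0 fell without WT replicate 1, 5 rose and 0 fell without WT replicate 2 or CRY2oe replicate 1, and 4 rose without CRY2oe replicate 2. In the auxin response list 6 fell without CRY2oe replicate 2. In the BR and GA list 5 fell without WT replicate 2, and 3 fell without CRY2oe replicate 2.

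Among root markers in CRY2oe, 1 of 18 rose and 6 fell (2 and 7 adjusted over the list alone, 1 and 7 rescaled). CASP5 stood at 39.8 ± 4.12 against 73.3 ± 4.72 FPKM. Camera put root marker genes below others (adjusted p = 0.0405, or adjusted p = 0.456 with estimated correlation). Their median was above 0 while their mean and test direction were below. Of 9 seed markers, 0 rose and 4 fell (0 and 5 adjusted over the list alone, 0 and 4 rescaled). EM1 stood at 1.21 ± 0.159 against 4.3 ± 0.568 FPKM. Camera put seed marker genes below others (adjusted p = 0.0072, or adjusted p = 0.409 with estimated correlation). Of 10 flowering genes, 1 rose and 3 fell (1 and 4 adjusted over the list alone, 1 and 4 rescaled), with a camera adjusted p of 0.155. FLC stood at 19.5 ± 0.643 against 59.8 ± 2.18 FPKM. Of 28 light signalling genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone, 8 and 5 rescaled). Of 29 shade genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone, 2 and 8 rescaled). Of 28 clock genes, 9 rose and 6 fell (10 and 7 adjusted over the list alone, 8 and 9 rescaled). Of 18 jasmonate genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, 2 and 3 rescaled). Of 12 salicylate defence genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, 1 and 1 rescaled). Of 20 cell cycle genes, 2 rose and 2 fell (1 and 2 adjusted over the list alone, 0 and 3 rescaled). The camera adjusted p of these 6 lists ranged from 0.174 to 0.946. Of 8 heat shock genes, 0 were called by limma (0 rose and 0 fell adjusted over the list alone, 0 and 1 rescaled) and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.075). HSP101 stood at 3.64 ± 0.135 against 4.17 ± 0.111 FPKM. Without WT replicate 1 HSP70-4 was called (limma adjusted p = 0.0226). For the clock, jasmonate and cell cycle lists the median and mean were above 0 and the test direction was down. The largest rises also included ATMRD1 (30.5 ± 2.19 against 0.0593 ± 0.0839 FPKM). The largest falls also included AT1G52690, AT3G02480 and OLEO2. The call was lost for AT3G02480 without any WT or cry2-1 library or CRY2oe replicate 2 (limma adjusted p up to 0.166) and for OLEO2 without CRY2oe replicate 2 (0.0678). The root marker call was lost after rescaling (camera adjusted p = 0.166, median -0.04), with only the libraries compared (0.102), without WT replicate 1 (0.718), cry2-1 replicate 2 (0.0514) or ubp12ubp13 replicate 1 (0.0559) or 2 (0.0622). The seed marker call was lost with the stricter filter (camera adjusted p = 0.674) or without WT replicate 1 (0.0709). The heat shock list passed with no filter (camera adjusted p = 0.0258) or without WT replicate 1 (0.0142). In the root marker list 3 rose and 6 fell without WT replicate 1. In the seed marker list 2 fell without WT replicate 1, and 1 fell without CRY2oe replicate 2. In the light signalling list 7 rose and 2 fell without WT replicate 2, 5 rose and 1 fell without CRY2oe replicate 1, and 6 rose and 1 fell without CRY2oe replicate 2. In the shade list 1 rose and 6 fell without either cry2-1 library or WT replicate 1, 1 rose and 5 fell without WT replicate 2, 0 rose and 7 fell without CRY2oe replicate 1, and 0 rose and 4 fell without CRY2oe replicate 2. In the clock list 8 rose and 3 fell without WT replicate 2, 6 rose and 3 fell without CRY2oe replicate 1, and 6 rose and 2 fell without CRY2oe replicate 2. In the jasmonate list 1 rose without CRY2oe replicate 2. In the salicylate defence list 2 rose without either ubp12ubp13 library or WT replicate 2. In the cell cycle list 6 rose without WT replicate 1, 0 rose without either CRY2oe library or WT replicate 2, and 1 rose without any cry2-1, UBP13oe or ubp12ubp13 library.

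Gain of UBP13 was examined by comparing UBP13oe with WT. The iron transporter gene IRT1 was at 16.9 ± 6.34 against 0.167 ± 0.0224 FPKM (log2 fold change 3.89 ± 0.20 (SE), limma adjusted p = 2.87e-05). AIR1 stood at 56.2 ± 2.96 against 8.5 ± 0.899 FPKM. The late embryogenesis gene LEA18 was at 7.27 ± 3.2 against 107 ± 24 FPKM and the tonoplast intrinsic protein gene BETA-TIP at 0.351 ± 0.0676 against 8.18 ± 0.0964 FPKM. limma called 8767 of 19956 genes, 7023 higher and 1744 lower. The median change of all genes was 0.15 on the log2 scale. After rescaling, with a median of 0.01, 3573 were called higher and 3807 lower, and 5316 were called with the same sign in both scalings. With nuclear genes alone 5415 were higher and 2320 lower. The count was 5613 without UBP13oe replicate 2.

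Of 20 cell cycle genes, 18 rose and 0 fell in UBP13oe (19 and 0 adjusted over the list alone, 16 and 0 rescaled). Camera put cell cycle genes above others (adjusted p = 4.19e-05, or adjusted p = 0.392 with estimated correlation). RNR1 stood at 15 ± 0.354 against 8.74 ± 0.864 FPKM and the kinesin HIK at 5.75 ± 0.269 against 2.46 ± 0.188 FPKM. In the tetrapyrrole list, 18 of 23 rose and 1 fell (18 and 1 adjusted over the list alone, 9 and 2 rescaled). Camera put tetrapyrrole genes above others (adjusted p = 0.00455, or adjusted p = 0.392 with estimated correlation). PORC stood at 54.9 ± 0.503 against 35 ± 0.796 FPKM. In the cell wall expansion list, 14 of 25 rose and 4 fell (14 and 4 adjusted over the list alone, 9 and 6 rescaled), with a camera adjusted p of 0.268. XTH17 stood at 122 ± 8.37 against 52.4 ± 7.01 FPKM. Of 36 auxin response genes, 2 rose and 11 fell (1 and 11 adjusted over the list alone, 0 and 15 rescaled). Camera put auxin response genes below others (adjusted p = 1.51e-05, or adjusted p = 0.381 with estimated correlation). IAA20 stood at 2.42 ± 0.232 against 5.15 ± 0.0216 FPKM. Of 29 shade genes, 4 rose and 10 fell (4 and 10 adjusted over the list alone, 2 and 12 rescaled). Camera put shade genes below others (adjusted p = 0.000734, or adjusted p = 0.381 with estimated correlation). XTH15 stood at 291 ± 3.5 against 738 ± 88.1 FPKM. Of 28 clock genes, 4 rose and 9 fell (4 and 9 adjusted over the list alone, 2 and 17 rescaled). Camera put clock genes below others (adjusted p = 3.46e-05, or adjusted p = 0.303 with estimated correlation). TOC1 stood at 75.3 ± 1.78 against 102 ± 5.19 FPKM. Of 10 flowering genes, 0 rose and 4 fell (0 and 4 adjusted over the list alone, 0 and 8 rescaled). Camera put flowering genes below others (adjusted p = 0.000957, or adjusted p = 0.295 with estimated correlation). FLC stood at 41.7 ± 0.265 against 59.8 ± 2.18 FPKM. Of 21 ABA and cold genes, 2 rose and 10 fell (2 and 12 adjusted over the list alone, 0 and 13 rescaled). Camera put ABA and cold genes below others (adjusted p = 2.79e-07, or adjusted p = 0.296 with estimated correlation). RAB18 stood at 55.1 ± 4.93 against 204 ± 61.3 FPKM. Of 9 seed markers, 0 rose and 6 fell (0 and 6 adjusted over the list alone, 0 and 6 rescaled). Camera put seed marker genes below others (adjusted p = 6.03e-06, or adjusted p = 0.307 with estimated correlation). EM1 stood at 0.304 ± 0.0361 against 4.3 ± 0.568 FPKM. The seed marker call was lost with the stricter filter (camera adjusted p = 0.118). In the cell wall expansion list 12 rose and 2 fell without UBP13oe replicate 2. In the auxin response list 7 fell without WT replicate 1, 0 rose and 9 fell without WT replicate 2, 0 rose and 8 fell without UBP13oe replicate 1, and 6 fell without UBP13oe replicate 2. In the shade list 6 fell without WT replicate 2, and 3 fell without UBP13oe replicate 2. In the clock list 2 rose and 8 fell without WT replicate 2 or UBP13oe replicate 2, and 2 rose and 9 fell without UBP13oe replicate 1. In the flowering list 2 fell without WT replicate 2. In the ABA and cold list 6 fell without WT replicate 2, 5 fell without UBP13oe replicate 1, and 0 rose and 6 fell without UBP13oe replicate 2. In the seed marker list 3 fell without UBP13oe replicate 2.

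Of 47 nuclear photosynthesis genes, 8 rose and 9 fell in UBP13oe (8 and 9 adjusted over the list alone, 6 and 18 rescaled). Camera put photosynthesis genes below others (adjusted p = 0.034, or adjusted p = 0.799 with estimated correlation). Their median and mean were above 0 while the test direction was down. LHCA6 stood at 85.2 ± 2.28 against 47.8 ± 2.78 FPKM. Of 18 root markers, 7 rose and 0 fell (7 and 0 adjusted over the list alone, 5 and 0 rescaled), with a camera adjusted p of 0.526. Of 18 jasmonate genes, 8 rose and 0 fell (11 and 0 adjusted over the list alone, 7 and 1 rescaled), with a camera adjusted p of 0.0812. OPR3 stood at 14.9 ± 0.145 against 9.74 ± 0.199 FPKM and AOC2 at 15.1 ± 1.89 against 5.94 ± 0.0574 FPKM. Of 12 salicylate defence genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 5 and 1 rescaled). Of 15 flavonoid genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone, 5 and 2 rescaled). Of 8 heat shock genes, 5 rose and 0 fell (5 and 0 adjusted over the list alone, 4 and 0 rescaled). Of 28 light signalling genes, 9 rose and 5 fell (10 and 7 adjusted over the list alone, 2 and 10 rescaled). Of 21 BR and GA genes, 4 rose and 3 fell (3 and 3 adjusted over the list alone, 2 and 8 rescaled). The camera adjusted p of these 5 lists ranged from 0.108 to 0.769. For the flavonoid, light signalling, and BR and GA lists, the median and mean were above 0 and the test direction was down. Another named rise was AT2G22942 (17.9 ± 9.93 against 0.336 ± 0.0729 FPKM). Other named falls were AT4G25580 (12.9 ± 3.63 against 90.7 ± 15.2 FPKM), AT5G01870, AT1G52690, AT1G47540 and AT3G02480. The call was lost for AT1G47540 without any library outside WT (limma adjusted p up to 0.153) and for AT3G02480 without WT replicate 1 or UBP13oe replicate 2 (0.0774). The photosynthesis call was lost with no filter (camera adjusted p = 0.0535), with the stricter filter (0.0615), without WT replicate 1 (0.767) or UBP13oe replicate 2 (0.134). The root marker list passed without WT replicate 1 (camera adjusted p = 0.0377). The jasmonate list passed after rescaling (camera adjusted p = 0.018), with only the libraries compared (0.0402) or with nuclear genes alone (0.0465). In the photosynthesis list 13 rose and 3 fell without WT replicate 1, 4 fell without UBP13oe replicate 1, and 2 fell without UBP13oe replicate 2. In the root marker list 11 rose without WT replicate 1, and 4 rose without UBP13oe replicate 1. In the salicylate defence list 6 rose and 2 fell without either ubp12ubp13 library. In the flavonoid list 3 rose without UBP13oe replicate 2. In the heat shock list 3 rose without WT replicate 1, and 2 rose without UBP13oe replicate 1. In the light signalling list 7 rose and 3 fell without UBP13oe replicate 1, and 5 rose and 2 fell without UBP13oe replicate 2. In the BR and GA list 2 rose without either UBP13oe library.

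The libraries labelled ubp12ubp13 were compared with WT to examine loss of both deubiquitinases. The reservation is that UBP12 and UBP13 transcript levels did not by themselves show that loss. QQS, an Arabidopsis-specific gene that affects starch content, was at 130.5 ± 8.11 against 0.454 ± 0.282 FPKM (log2 fold change 6.51 ± 0.28 (SE), limma adjusted p = 1.02e-06), IRT1 at 60.2 ± 6.55 against 0.167 ± 0.0224 FPKM and the expansin gene EXPA2 at 58.5 ± 16 against 2.54 ± 0.0276 FPKM. The threonine aldolase gene THA1 was at 5.44 ± 1.2 against 185 ± 9.28 FPKM and the stress-inducible linker histone gene HIS1-3 at 10.2 ± 2.48 against 225 ± 13.6 FPKM. limma called 11344 of 19955 genes, 6905 higher and 4439 lower in the libraries labelled ubp12ubp13. Rescaled, 5574 were higher and 5610 lower, and 10013 were called with the same sign in both scalings. Other named rises were AT2G22942 (92.7 ± 27.8 against 0.336 ± 0.0729 FPKM), AT1G43910, AT1G21520 and the pseudogenes AT1G21525 and AT2G16367, and another named fall was AT4G25580 (3.27 ± 0.74 against 90.7 ± 15.2 FPKM).

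Of 23 tetrapyrrole genes, 22 rose and 0 fell in the libraries labelled ubp12ubp13 (22 and 0 adjusted over the list alone, 21 and 0 rescaled), with a median 1.04 above that of all genes on the log2 scale. Camera put tetrapyrrole genes above others (adjusted p = 1.06e-10, or adjusted p = 0.295 with estimated correlation). CHLH was at 485 ± 18.7 against 128 ± 5.78 FPKM and CAO at 147 ± 3.71 against 56 ± 1.00 FPKM. Of 47 nuclear photosynthesis genes, 41 rose and 3 fell (41 and 3 adjusted over the list alone, 33 and 3 rescaled). Camera put photosynthesis genes above others (adjusted p = 5.61e-08, or adjusted p = 0.445 with estimated correlation). PSBS stood at 1150.0 ± 12.2 against 455 ± 18.9 FPKM and LHCA6 at 154 ± 0.541 against 47.8 ± 2.78 FPKM, and the plastid-encoded share of FPKM was higher too. RBCS2B of the Rubisco small subunit was at 4478 ± 16 against 1218 ± 81.4 FPKM. Of 15 flavonoid genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone, 13 and 1 rescaled). Camera put flavonoid genes above others (adjusted p = 0.000728, or adjusted p = 0.307 with estimated correlation). CHS stood at 53.2 ± 11.4 against 7.57 ± 2.02 FPKM. For jasmonate genes, 14 of 18 rose and 2 fell (14 and 2 adjusted over the list alone, 12 and 3 rescaled). Camera put jasmonate genes above others (adjusted p = 0.0145, or adjusted p = 0.307 with estimated correlation). LOX3 stood at 2.74 ± 0.0586 against 0.323 ± 0.0386 FPKM and AOS at 33.7 ± 3.61 against 16.2 ± 0.0716 FPKM. Of 12 salicylate defence genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, 7 and 0 rescaled). Camera put salicylate defence genes above others (adjusted p = 0.017, or adjusted p = 0.392 with estimated correlation). ICS1, the salicylate synthesis gene, was at 40.9 ± 7.08 against 3.64 ± 0.537 FPKM. PBS3 stood at 5.90 ± 0.0120 FPKM and was listed at 0 in WT. The salicylate defence call was lost with the stricter filter (camera adjusted p = 0.18) or without ubp12ubp13 replicate 2 (0.0624). In the photosynthesis list 41 rose and 1 fell without ubp12ubp13 replicate 2.

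Of 36 auxin response genes, 4 rose and 24 fell in the libraries labelled ubp12ubp13 (4 and 24 adjusted over the list alone, 4 and 26 rescaled). Camera put auxin response genes below others (adjusted p = 4.10e-06, or adjusted p = 0.381 with estimated correlation). IAA6 stood at 2.51 ± 0.393 against 9.98 ± 0.354 FPKM. Of 29 shade genes, 6 rose and 11 fell (6 and 11 adjusted over the list alone, 5 and 14 rescaled), with PIF4, a growth-promoting transcription factor, at 22.1 ± 0.900 against 48.5 ± 0.943 FPKM and ST2A at 17.3 ± 0.825 against 91 ± 18 FPKM. Camera put shade genes below others (adjusted p = 0.0185, or adjusted p = 0.456 with estimated correlation). Of 21 BR and GA genes, 2 rose and 11 fell (2 and 11 adjusted over the list alone, 2 and 13 rescaled), the brassinosteroid synthesis gene CPD being at 147 ± 9.56 against 297 ± 3.77 FPKM. Camera put BR and GA genes below others (adjusted p = 0.00232, or adjusted p = 0.296 with estimated correlation). Of 21 ABA and cold genes, 1 rose and 13 fell (1 and 13 adjusted over the list alone, 1 and 15 rescaled). Camera put ABA and cold genes below others (adjusted p = 0.000144, or adjusted p = 0.346 with estimated correlation). COR47 stood at 547 ± 11.9 against 1373 ± 86.2 FPKM. Of 25 cell wall expansion genes, 5 rose and 12 fell (5 and 12 adjusted over the list alone, 5 and 14 rescaled). Camera put cell wall expansion genes below others (adjusted p = 0.0456, or adjusted p = 0.346 with estimated correlation). XTH24 stood at 376 ± 4.78 against 992 ± 13.1 FPKM and, in the other direction, EXPA1 at 134 ± 1.48 against 52 ± 2.67 FPKM. Of 18 root markers, 9 rose and 6 fell (9 and 6 adjusted over the list alone, 8 and 6 rescaled), with a camera adjusted p of 0.66. CASP5 stood at 31.8 ± 2.04 against 73.3 ± 4.72 FPKM. The median and mean of the root markers were above 0 while the test direction was down. Of 28 clock genes, 10 rose and 16 fell (11 and 16 adjusted over the list alone, 9 and 16 rescaled), with a camera adjusted p of 0.0656. CCA1 stood at 50.2 ± 2.27 against 17.9 ± 0.804 FPKM and TOC1 at 49 ± 0.113 against 102 ± 5.19 FPKM. Of 28 light signalling genes, 13 rose and 10 fell (15 and 10 adjusted over the list alone, 13 and 11 rescaled). Of 10 flowering genes, 2 rose and 5 fell (2 and 5 adjusted over the list alone, 2 and 6 rescaled). Of 8 heat shock genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone, 3 and 0 rescaled). Of 20 cell cycle genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone, 9 and 2 rescaled). Of 9 seed marker genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone, 1 and 1 rescaled). The camera adjusted p of these 5 lists ranged from 0.0905 to 0.787. The heat shock median lay below 0 with a mean and test above, and the seed marker median and mean above 0 with a test direction below. The shade call was lost with the stricter filter (camera adjusted p = 0.0503) or without ubp12ubp13 replicate 2 (0.0692). The cell wall expansion call was lost with the stricter filter (camera adjusted p = 0.132), after rescaling (0.0772), without WT replicate 1 (0.0978), UBP13oe replicate 1 (0.0519) or 2 (0.051) or ubp12ubp13 replicate 2 (0.0793). The clock list passed with no filter (camera adjusted p = 0.037) or with nuclear genes alone (0.0482). The flowering list passed with the stricter filter (camera adjusted p = 0.0379). The cell cycle list passed without WT replicate 1 (camera adjusted p = 0.0186) or ubp12ubp13 replicate 2 (0.0455). In the shade list 7 fell without WT replicate 2. In the BR and GA list 7 fell without WT replicate 2 or ubp12ubp13 replicate 2. In the cell cycle list 7 rose without WT replicate 2. In the seed marker list 2 rose without WT replicate 1 or ubp12ubp13 replicate 1, and 1 rose and 4 fell without WT replicate 2.

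**Figure D2:**
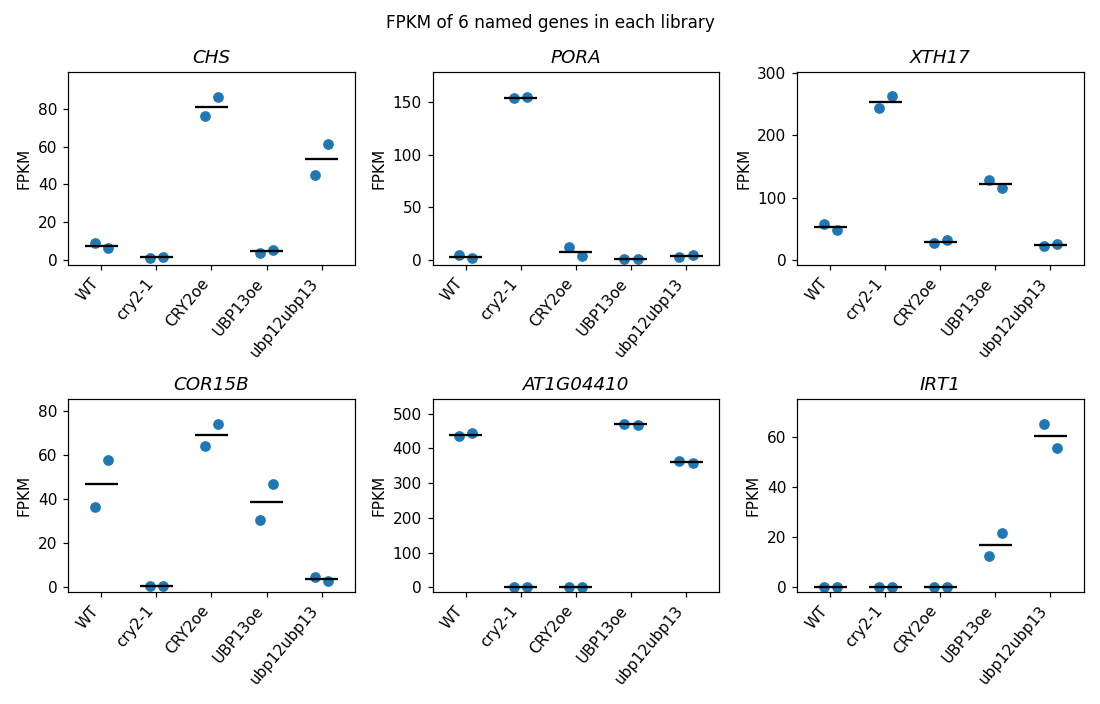
FPKM (vertical axes, linear) of CHS, PORA, XTH17, COR15B, AT1G04410 and IRT1 in the 2 libraries of each of the 5 genotypes (points), with the mean as a bar. CHS is highest in CRY2oe (81.2 FPKM) among these means, XTH17 in cry2-1, and AT1G04410 is near 0 in cry2-1 and CRY2oe.

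CRY2oe and cry2-1 were compared directly to set gain against loss of CRY2 without WT. CHS was at 81.2 ± 7.15 against 1.34 ± 0.0556 FPKM in CRY2oe and cry2-1 (log2 fold change 5.13 ± 0.19 (SE), limma adjusted p = 1.71e-06) and COR15B at 69.1 ± 6.89 against 0.381 ± 0.0697 FPKM, while XTH17 was at 29.1 ± 2.99 against 252 ± 13.4 FPKM. limma called 7470 of 19956 genes, 2685 higher and 4785 lower in CRY2oe, and 3510 higher and 3360 lower after rescaling, with 6045 called with the same sign in both. Of 47 photosynthesis genes, 38 rose and 2 fell in CRY2oe (40 and 2 adjusted over the list alone, 40 and 0 rescaled). Camera put photosynthesis genes above others (adjusted p = 2.70e-15, or adjusted p = 0.365 with estimated correlation). PSBO2 stood at 536 ± 16.9 against 284 ± 2.45 FPKM. Of 15 flavonoid genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, 11 and 0 rescaled). Camera put flavonoid genes above others (adjusted p = 5.61e-08, or adjusted p = 0.295 with estimated correlation). F3H stood at 25.5 ± 1.74 against 2.48 ± 0.774 FPKM. Of 28 clock genes, 15 rose and 2 fell (16 and 2 adjusted over the list alone, 19 and 1 rescaled). Camera put clock genes above others (adjusted p = 2.53e-07, or adjusted p = 0.295 with estimated correlation). FKF1 stood at 18.9 ± 0.227 against 5.45 ± 0.501 FPKM. Of 28 light signalling genes, 11 rose and 6 fell (12 and 6 adjusted over the list alone, 12 and 6 rescaled). Camera put light signalling genes above others (adjusted p = 0.00533, or adjusted p = 0.307 with estimated correlation). BIC1 stood at 18.5 ± 1.1 against 2.35 ± 0.355 FPKM. Of 36 auxin response genes, 0 rose and 23 fell in CRY2oe (0 and 24 adjusted over the list alone, 0 and 21 rescaled). Camera put auxin response genes below others (adjusted p = 5.93e-06, or adjusted p = 0.381 with estimated correlation). IAA19 stood at 26.5 ± 1.65 against 96.2 ± 4.57 FPKM. Of 25 cell wall expansion genes, 3 rose and 18 fell (3 and 18 adjusted over the list alone, 3 and 15 rescaled). Camera put cell wall expansion genes below others (adjusted p = 0.00016, or adjusted p = 0.295 with estimated correlation). Of 29 shade genes, 2 rose and 14 fell (2 and 16 adjusted over the list alone, 2 and 12 rescaled). Camera put shade genes below others (adjusted p = 0.00255, or adjusted p = 0.386 with estimated correlation). Of 23 tetrapyrrole genes, 0 rose and 17 fell (0 and 18 adjusted over the list alone, 0 and 16 rescaled). Camera put tetrapyrrole genes below others (adjusted p = 4.16e-06, or adjusted p = 0.303 with estimated correlation). PORB stood at 132 ± 1.42 against 515 ± 32.1 FPKM. Of 20 cell cycle genes, 0 rose and 18 fell (0 and 18 adjusted over the list alone, 0 and 15 rescaled). Camera put cell cycle genes below others (adjusted p = 5.29e-06, or adjusted p = 0.381 with estimated correlation). Of 8 heat shock genes, 0 rose and 5 fell (0 and 7 adjusted over the list alone, 0 and 5 rescaled). Camera put heat shock genes below others (adjusted p = 0.0218, or adjusted p = 0.419 with estimated correlation). The heat shock call was lost with the stricter filter (camera adjusted p = 0.283). In the photosynthesis list 34 rose and 0 fell without cry2-1 replicate 2 or CRY2oe replicate 2, and 32 rose and 0 fell without CRY2oe replicate 1. In the cell wall expansion list 1 rose and 15 fell without cry2-1 replicate 2. In the heat shock list 3 fell without either cry2-1 library or CRY2oe replicate 1.

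Of 18 root markers, 5 rose and 7 fell in CRY2oe against cry2-1 (5 and 7 adjusted over the list alone, 5 and 7 rescaled), with a camera adjusted p of 0.674, a median above 0 and a mean and test direction below. CASP5 stood at 39.8 ± 4.12 against 157 ± 2.77 FPKM. Of 21 ABA and cold genes, 8 rose and 6 fell (9 and 7 adjusted over the list alone, 8 and 5 rescaled), with a camera adjusted p of 0.0639. COR15A stood at 16.5 ± 1.95 against 0.461 ± 0.0711 FPKM. Of 10 flowering genes, 3 rose and 2 fell (3 and 2 adjusted over the list alone, 3 and 1 rescaled). Of 18 jasmonate genes, 1 rose and 5 fell (3 and 6 adjusted over the list alone, 3 and 4 rescaled). Of 12 salicylate defence genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 2 rescaled). Of 20 BR and GA genes, 2 rose and 12 fell (2 and 12 adjusted over the list alone, 4 and 9 rescaled). The camera adjusted p of these 4 lists ranged from 0.108 to 0.804. Of 9 seed markers, 0 were called by limma (0 rose and 0 fell adjusted over the list alone, 0 and 0 rescaled) and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.607), though EM1 was called without ubp12ubp13 replicate 1 or 2 (limma adjusted p up to 0.0367) and PER1 without CRY2oe replicate 1 (0.0252). The root marker list passed with the stricter filter (camera adjusted p = 0.0136, median -1.37). The ABA and cold list passed without cry2-1 replicate 1 (camera adjusted p = 0.0282), CRY2oe replicate 2 (0.0434) or with nuclear genes alone (0.0439). The BR and GA list passed with failed estimates as 0 (camera adjusted p = 0.0337). In the root marker list 0 rose and 7 fell without cry2-1 replicate 1, 3 rose and 7 fell without cry2-1 replicate 2, and 1 rose and 7 fell without either CRY2oe library. In the jasmonate list 3 fell without CRY2oe replicate 1, 2 fell without CRY2oe replicate 2, and 3 rose and 5 fell without either ubp12ubp13 library. In the salicylate defence list 1 fell without cry2-1 replicate 1 or CRY2oe replicate 1. In the BR and GA list 4 fell without cry2-1 replicate 1, and 6 fell without cry2-1 replicate 2 or CRY2oe replicate 2.

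The libraries labelled ubp12ubp13 were compared with UBP13oe in the same way, with the reservation on the label given above. CHS was at 53.2 ± 11.4 against 4.49 ± 0.899 FPKM (limma adjusted p = 7.18e-06), ICS1 at 40.9 ± 7.08 against 5.58 ± 0.126 FPKM and XTH17 at 24 ± 1.66 against 122 ± 8.37 FPKM in the libraries labelled ubp12ubp13 and in UBP13oe. limma called 10561 of 19956 genes, 4158 higher and 6403 lower in the libraries labelled ubp12ubp13, and 5136 higher and 5302 lower after rescaling, with 9459 called with the same sign in both. With nuclear genes alone 5292 were higher and 5107 lower. Of 47 photosynthesis genes, 41 rose and 1 fell (44 and 1 adjusted over the list alone, 44 and 1 rescaled). Camera put photosynthesis genes above others (adjusted p = 4.19e-16, or adjusted p = 0.346 with estimated correlation). LHCB4.3 stood at 32.3 ± 3.37 against 7.96 ± 0.668 FPKM. Of 23 tetrapyrrole genes, 22 rose and 0 fell (22 and 0 adjusted over the list alone, 22 and 0 rescaled). Camera put tetrapyrrole genes above others (adjusted p = 1.14e-14, or adjusted p = 0.295 with estimated correlation). HEMA1 stood at 253 ± 9.38 against 126 ± 6.22 FPKM. Of 15 flavonoid genes, 12 rose and 0 fell (12 and 0 adjusted over the list alone, 12 and 0 rescaled). Camera put flavonoid genes above others (adjusted p = 1.37e-05, or adjusted p = 0.296 with estimated correlation). Of 12 salicylate defence genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, 7 and 1 rescaled). Camera put salicylate defence genes above others (adjusted p = 0.0109, or adjusted p = 0.386 with estimated correlation). Of 9 seed markers, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 5 and 0 rescaled). Camera put seed marker genes above others (adjusted p = 0.00243, or adjusted p = 0.388 with estimated correlation). OLEO2 stood at 9.94 ± 1.8 against 0.364 ± 0.237 FPKM. Of 25 cell wall expansion genes, 5 rose and 16 fell (5 and 16 adjusted over the list alone, 5 and 14 rescaled). Camera put cell wall expansion genes below others (adjusted p = 0.0201, or adjusted p = 0.307 with estimated correlation). XTH4 stood at 672 ± 65.1 against 2128 ± 0.962 FPKM. The salicylate defence call was lost with the stricter filter (camera adjusted p = 0.293, median -0.06). The seed marker call was lost with the stricter filter (camera adjusted p = 0.0688). The cell wall expansion call was lost with the stricter filter (camera adjusted p = 0.052).

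In the same comparison, 0 of 21 BR and GA genes rose and 12 fell (0 and 12 adjusted over the list alone, 1 and 9 rescaled). Camera put BR and GA genes below others (adjusted p = 0.0303, or adjusted p = 0.346 with estimated correlation). BR6OX1 stood at 3.25 ± 0.600 against 8.23 ± 0.523 FPKM. Of 20 cell cycle genes, 0 rose and 12 fell (0 and 12 adjusted over the list alone, 0 and 11 rescaled). Camera put cell cycle genes below others (adjusted p = 0.0356, or adjusted p = 0.668 with estimated correlation). Of 36 auxin response genes, 7 rose and 19 fell (7 and 20 adjusted over the list alone, 7 and 18 rescaled). Camera put auxin response genes below others (adjusted p = 0.0456, or adjusted p = 0.668 with estimated correlation). IAA3 stood at 40.5 ± 2.65 against 93 ± 5.87 FPKM. Of 18 root markers, 6 rose and 6 fell (7 and 6 adjusted over the list alone, 8 and 6 rescaled), with a camera adjusted p of 0.879, with a median above 0 and a mean and test direction below. Of 28 light signalling genes, 12 rose and 8 fell (12 and 9 adjusted over the list alone, 13 and 7 rescaled). Of 29 shade genes, 5 rose and 9 fell (5 and 9 adjusted over the list alone, 6 and 9 rescaled). Of 28 clock genes, 11 rose and 14 fell (11 and 14 adjusted over the list alone, 11 and 11 rescaled). Of 10 flowering genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone, 3 and 3 rescaled). Of 18 jasmonate genes, 6 rose and 3 fell (6 and 3 adjusted over the list alone, 9 and 3 rescaled). Of 21 ABA and cold genes, 6 rose and 8 fell (7 and 9 adjusted over the list alone, 7 and 7 rescaled). Of 8 heat shock genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, 2 and 4 rescaled). The camera adjusted p of these 7 lists ranged from 0.081 to 0.867. Median and mean differed in sign for light signalling, clock and flowering genes, whose tests pointed up, up and down. The BR and GA call was lost with only the libraries compared (camera adjusted p = 0.0537), without UBP13oe replicate 1 (0.0572), ubp12ubp13 replicate 2 (0.0705) or with failed estimates as 0 (0.0522). The cell cycle call was lost with the stricter filter (camera adjusted p = 0.0552) or without ubp12ubp13 replicate 2 (0.0913). The auxin response call was lost with the stricter filter (camera adjusted p = 0.0601), with only the libraries compared (0.0626), without WT replicate 1 (0.0555) or 2 (0.0544), cry2-1 replicate 1 (0.0528) or 2 (0.0547), UBP13oe replicate 1 (0.147) or ubp12ubp13 replicate 2 (0.129). The jasmonate list passed with no filter (camera adjusted p = 0.0275). In the auxin response list 3 rose and 20 fell without UBP13oe replicate 2, and 4 rose and 22 fell without ubp12ubp13 replicate 1. In the root marker list 3 rose without any cry2-1 or CRY2oe library or ubp12ubp13 replicate 2, and 1 rose without either UBP13oe library or ubp12ubp13 replicate 1. In the shade list 3 rose and 9 fell without UBP13oe replicate 2. In the flowering list 3 fell without UBP13oe replicate 1, 1 rose and 2 fell without UBP13oe replicate 2, 1 rose and 4 fell without ubp12ubp13 replicate 1, and 2 fell without ubp12ubp13 replicate 2. In the jasmonate list 5 rose and 1 fell without UBP13oe replicate 2. In the ABA and cold list 0 rose and 6 fell without UBP13oe replicate 1, 3 rose and 6 fell without UBP13oe replicate 2, 3 rose and 7 fell without ubp12ubp13 replicate 1, and 2 rose and 7 fell without ubp12ubp13 replicate 2. In the heat shock list 2 fell without UBP13oe replicate 1 or ubp12ubp13 replicate 1.

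**Figure D3:**
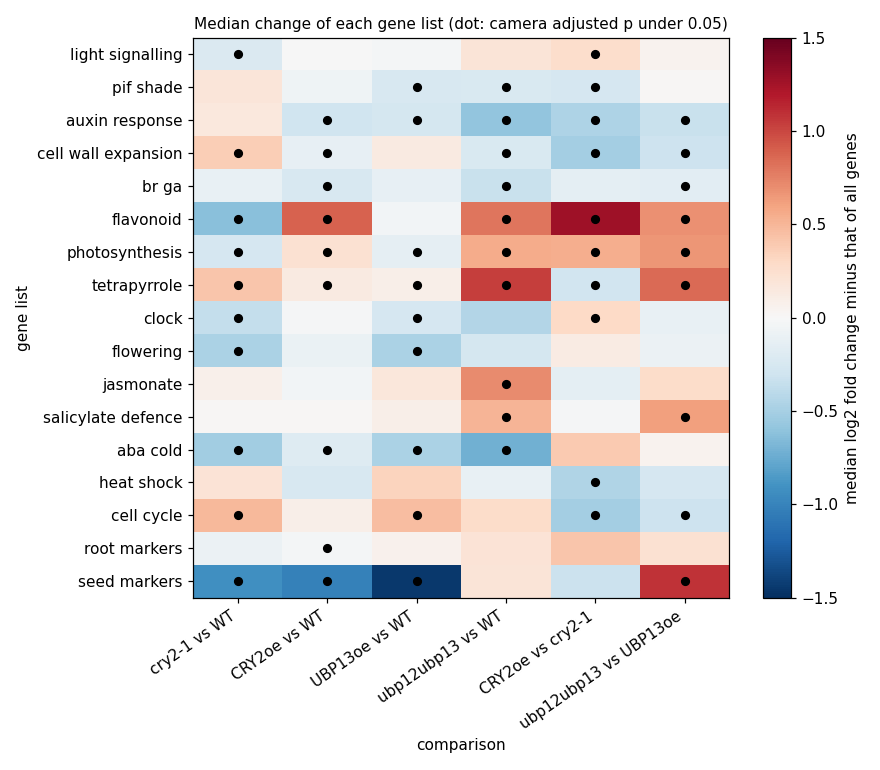
Median log2 fold change of each of 17 gene lists (vertical axis), minus the median of all genes, in 6 comparisons (horizontal axis), as colour from blue (lower) to red (higher). Dots mark the 57 of 102 tests with a camera adjusted p under 0.05 at the preset correlation, of which 0 passed with an estimated correlation (15 of 102 at an unadjusted p under 0.05), and the flavonoid and photosynthesis lists are red in CRY2oe against cry2-1 and in ubp12ubp13 against UBP13oe.

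With the reservation on the label, changes in CRY2oe against cry2-1 were set beside those in ubp12ubp13 against UBP13oe. CHS was higher in both. XTH17, the oleosin gene OLEO3 (3.58 ± 0.0645 against 29.96 ± 2.15 FPKM, and 1.01 ± 0.582 against 8.69 ± 0.0419 FPKM) and the cell wall protein gene ATPRP2 (44.2 ± 10.5 against 215 ± 9.18 FPKM, and 36 ± 6.22 against 176 ± 0.955 FPKM) were lower in both. Opposite changes were found for COR15B, higher in CRY2oe and lower in the libraries labelled ubp12ubp13 (3.88 ± 1.27 against 38.7 ± 11.8 FPKM), and likewise for GRP9 (87.3 ± 7.01 against 19.97 ± 1.55 FPKM, and 4.14 ± 1.51 against 36 ± 3.83 FPKM), XTH25 and AT1G22690. AT1G52690 changed the other way in both, and its call in CRY2oe against cry2-1 was lost without cry2-1 replicate 1. Both comparisons called 1104 genes higher and 2507 lower, against 559 and 1535 for independent lists. A further 643 and 645 were called oppositely, against 861 and 997. Rescaled, these were 1556, 1724, 737 and 526, against 903, 893, 932 and 864. Across 19947 genes, not independent replicates, both sets of fold changes, which share no library, correlated at Pearson r = 0.233 and Spearman rho = 0.258, with a covariance of 0.0613. Of 2520 assignments of the 8 libraries to these roles, 720 (a share of 0.286) gave r at least as high, the highest other being 0.771. Most split replicates of a genotype, which can itself raise r, so this share is no chance level. Other pairings of whole genotypes gave r = 0.0452 and, for CRY2oe minus ubp12ubp13 with UBP13oe minus cry2-1, -0.193. Reversing a difference turns its sign, so in size it is near 0.233.

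Against the shared WT libraries, fold changes of UBP13oe and cry2-1 had a covariance of 0.0819 and those of ubp12ubp13 and CRY2oe 0.0968. The opposite pairings gave 0.0563 for UBP13oe and CRY2oe and 0.0611 for ubp12ubp13 and cry2-1. Unchanged groups sharing WT (50 simulations) gave a covariance of 0.0257, a correlation of 0.495 and 0 shared calls. That covariance may be low, as WT replicates differed most (SD 0.354, others up to 0.347). The covariances minus it, so perhaps too large, were 0.0562, 0.0711, 0.0305 and 0.0354, and the correlations were 0.445, 0.435, 0.378 and 0.222. With a different WT library in each comparison the covariances were 0.0505, 0.0654, 0.0249 and 0.0297. Without WT replicate 1 or 2 those of the opposite pairings rose to as much as 0.0885 and 0.0982. With both WT libraries, CRY2oe and cry2-1 gave 0.0659, above the opposite pairings, and ubp12ubp13 and UBP13oe 0.0999, the highest. UBP13oe and cry2-1 shared 4197 genes called higher and 818 called lower against WT, against 2227 and 206 for independent lists. ubp12ubp13 and CRY2oe shared 2127 and 1270, against 1142 and 427. UBP13oe and CRY2oe shared 2209 and 528, against 1161 and 168, and ubp12ubp13 and cry2-1 2982 and 1000, against 2190 and 525. Rescaled, these pairs shared 1708 and 2129 (against 590.1 and 776), 1281 and 2066 (604 and 844), 1039 and 1414 (387 and 572), and 1410 and 2088 (921 and 1143). Splitting WT leaves 1 library on each side, so part of each excess may come from the shared controls. Compared directly, limma called 5785 genes between UBP13oe and cry2-1, 3440 higher and 2345 lower in UBP13oe. With nuclear genes alone 2514 were higher and 4124 lower. Between ubp12ubp13 and CRY2oe it called 9977 genes, 5278 higher and 4699 lower.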

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

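Failed estimates as 0 and nuclear genes alone, rescaled to the nuclear total, were chosen after seeing the data, and the other alternatives before. The stricter filter kept 86 of 102 list results, lost 13 calls and gained 3, and the rescaling kept 96, lost 4 and gained 2. With an estimated correlation camera called 0 lists (15 of 102 at an unadjusted p under 0.05). Of 529 results for named genes, the rescaling kept 501 and fitting only the libraries compared kept 489, which gave 2194 calls for CRY2oe against WT. Without 1 library, CRY2oe against WT had 2152 to 5104 calls, UBP13oe against WT 5613 to 8805 and UBP13oe against cry2-1 3442 to 6146, and 77 of the 529 gene results changed their call. Taking failed estimates as 0 gave UBP12 in ubp12ubp13 a log2 fold change of -0.85.

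The correlation of CRY2oe minus cry2-1 with ubp12ubp13 minus UBP13oe was 0.203 with a pseudocount of 0.1, 0.248 with the stricter filter, 0.243 with nuclear genes and 0.212 to 0.236 without 1 library. For UBP13oe and cry2-1, ubp12ubp13 and CRY2oe, UBP13oe and CRY2oe, and ubp12ubp13 and cry2-1, the covariances were 0.159, 0.178, 0.119 and 0.122 with a pseudocount of 0.1. With a different WT library in each comparison they were 0.0505, 0.0654, 0.0249 and 0.0297. Without 1 library they ran from 0.0792 to 0.115, 0.0937 to 0.133, 0.0537 to 0.0885 and 0.0548 to 0.0982, the highest always without WT replicate 1. With no filter, that of ubp12ubp13 and CRY2oe was 0.0812. Fewer WT libraries add control variance by construction, and the cause of the other shifts was not tested.

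Replicate numbers did not pair the libraries, since same-numbered deviations correlated at -0.0884 to 0.146. With the replicate block, calls were 8493, 5030, 8634 and 11277 for cry2-1, CRY2oe, UBP13oe and ubp12ubp13 against WT, and 57 lists were called, with root markers in CRY2oe lost (camera adjusted p = 0.0519) and shade genes in cry2-1 gained (0.0425). Count-based alternatives were not run. Depth limits genes near 0.0962 to 0.189 FPKM (3 fragments at 1 kb).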

Other observations

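All tests in this part were chosen after the results they bear on had been seen, and the Casparian strip and root hair gene sets were written after that too.

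Genes of organelles and of root cell layers moved with genotype. Of 49 plastid-encoded genes of 300 bp or more, 46 rose in cry2-1, 45 in CRY2oe, 33 in UBP13oe and 47 in the libraries labelled ubp12ubp13 (median log2 fold changes from 0.80 in UBP13oe to 1.89 in cry2-1), while 1, 0, 4 and 0 fell (46, 45, 31 and 44 rose and 1, 0, 6 and 0 fell rescaled). Of 25 mitochondrial genes, 16, 8, 4 and 15 rose and 0, 3, 11 and 0 fell. Of 6 Casparian strip genes of the endodermis, 6 rose in cry2-1 and 5 in UBP13oe (6 and 4 rescaled), while 5 fell in CRY2oe and 6 in the libraries labelled ubp12ubp13 (6 and 6 rescaled). Of 6 root hair genes, 1 fell in cry2-1 (3 rescaled) and 5 rose in the libraries labelled ubp12ubp13 (4 rescaled).

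AT1G04410 and AT1G04420, beside CRY2, were near 0 in cry2-1 and CRY2oe. A response in step with CRY2 level is argued against. CRY2 was at 0 and 0.0187 FPKM in cry2-1 and 3923 and 3808 in CRY2oe (WT 110 and 120). Other responses stay open. A chromosome segment beside CRY2 altered in both cry2-1 and CRY2oe is a candidate explanation, since all 2 nuclear genes under 1% of WT in both genotypes start within 10 kb of CRY2, and CRY2oe may then carry that segment of cry2-1. Whether both lines share a line background beyond that segment stays open, since the pair stood apart from the other genotypes by 8-fold or more on 1 further gene (ATMRD1), and another of the 10 pairs, UBP13oe and ubp12ubp13, also on 1 (IRT1). That tie meets the bound first set against a shared background, but the reading changed after seeing the counts, because 1 against 1 lies within counting error.

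Plastid-encoded transcripts were higher in cry2-1, CRY2oe and the libraries labelled ubp12ubp13. Carry-over of RNA without poly(A) tails that raises every plastid transcript alike is argued against as the whole cause in cry2-1 and CRY2oe. There the SD of the change over plastid genes was 4.82 and 4.24 times its replicate SD. That ratio was first computed on all plastid genes and then on those of 5 FPKM or more in WT. The replicate SD was that expected of a difference between genotype means. It is smaller than the SD of the difference between replicates, which the bound named. The ratio of 2.51 in the libraries labelled ubp12ubp13 would miss the bound on the larger SD, so the question stays open there. Carry-over as part of the cause cannot be told apart from a change in plastid transcripts, since mitochondrial genes moved by as little as 0.152 of the plastid median, between the bounds set. In UBP13oe, which is outside this pattern although 33 plastid genes rose there, mitochondrial genes went the other way, by -0.283 of the plastid median. Such carry-over may differ between library preparations, and no biological explanation was tested.

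Casparian strip genes were higher in cry2-1 and UBP13oe and lower in CRY2oe and the libraries labelled ubp12ubp13, with median log2 fold changes of 0.85, 0.50, -0.69 and -0.93. A different share of root in the seedlings is argued against as the whole cause over the 4 genotypes, because root hair genes had medians of opposite sign in 3 genotypes (-0.46 in cry2-1, 0.22 in CRY2oe and 0.81 in the libraries labelled ubp12ubp13). This rests mainly on the last, since limma called 0 of 6 root hair genes in CRY2oe and in UBP13oe (0 at an unadjusted p under 0.05) and 1 in cry2-1. In UBP13oe their median had the same sign (0.17), so root share stays open there. A change in the endodermis or in root age with genotype may account for it and stays open as an untested hypothesis.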
